A study of Mus musculus with 3 samples.

How the data were processed

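Total RNA from JB6 P+ cells was sequenced in 3 libraries: control, TPA, and CDDO+TPA. DNA methylation from the same project was not analysed here. The authors deposited whole-number read counts per gene symbol, not normalized, in 1 table for the series. Per the file headers, the counts were made with featureCounts 1.5.3 on a UCSC mm10 annotation with the option that keeps primary alignments. Per the file headers, no option for strand, read pairs or multi-mapping reads was given. HISAT2, Picard and DESeq are named in the submitters' processing notes without a version, with mm10 as the genome build. The column names of the table, per the file headers, carry a mark of duplicate removal. How duplicates were removed and whether replicates were pooled is not given in the sources used here. The command in the header lists 7 alignment files, and the counts used here are those of the 3 columns present.

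Each column was matched to a sample by its name. The control and TPA columns name their treatment. The CDDO column names CDDO without TPA, and it was taken as CDDO+TPA, the only sample whose labels name CDDO; if that column held another treatment, every statement on CDDO+TPA would describe that treatment.

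These steps affect the values. Where duplicates are removed by position, the reads that an abundant gene can hold are capped, which can narrow its fold changes. Counting without strand cannot separate reads where exons of genes on opposite strands overlap. The spans of Veph1 and Ptx3, Timp3 and Syn3, Angpt2 and Mcph1, Vil1 and Usp37, Itga7 and Mettl7b, and Itgb4 and Galk1 overlap on opposite strands. So do those of Ankrd37 and Ufsp2, Cryab and Hspb2, Slc34a1 and Pfn3, Fosl1 and Ccdc85b, and Dnmt3a and Dnmt3aos. Other opposite-strand overlaps, such as those with microRNA genes, are not listed. Whether the exons of these pairs overlap was not examined. Counting the primary alignment of a read that maps to several places divides reads among near-identical copies by the aligner's choice, so values of single members of the Gsta, Prl2c, Hspa1, Saa, Mcpt and Serpin families are uncertain. Sums over Gsta1, Gsta2 and Gm3776, over the Prl2c genes and over Hspa1a and Hspa1b are given for that reason.

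Library totals were scaled by the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 0.978, 1.02 and 1.00 for control, TPA and CDDO+TPA. Log2 CPM was computed with a prior count of 2 scaled to library size, and a log2 fold change is a difference of these values, which understates the change of genes with few reads. Folds printed as such are ratios of CPM without a prior count, and their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals of the ratio of 2 counts. They cover counting error only, since reads are not independent molecules and no spread between cultures was measured. A fold against a library at 0 counts is given as at least its ratio to a floor of 3 counts in that library. This ratio leaves out the counting error of the other library and can exceed the lower end of the 95% interval. With 8190078, 7813035 and 7872089 reads, that floor lies at 0.374, 0.377 and 0.380 CPM. CPM intervals in the plot of single genes are exact Poisson intervals.

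Genes with at least 1 CPM in at least 1 of the 3 libraries entered, 13100 of 24421. With 1 library per group no p-value was computed. A gene was past the size rule at a log2 fold change of at least 1 in size with a counting interval that excluded 1, and the rule describes these libraries, not the conditions. The comparisons were TPA with control, CDDO+TPA with TPA, and CDDO+TPA with control, and the genes past the rule in opposite directions in TPA against control and CDDO+TPA against TPA were counted.

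Before the data were examined, 26 gene lists were fixed. They cover NRF2 targets, AP-1, NF-kB and TGF-beta genes, matrix proteases, cytokines, interferon response, cell cycle, CDK inhibitors and p53 targets, EGF receptor ligands and ERK feedback, skin tumour promotion genes, cholesterol synthesis, stress responses, heat shock, DNA and histone modifying enzymes, glycolysis, oxidative phosphorylation, complement and acute phase, motility and ribosomal proteins. Keratinocyte, mesenchymal, leukocyte, endothelial, and melanocyte and Schwann cell markers were also fixed. For each list with at least 5 measured members, the median log2 fold change was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. A list stood apart below percentile 2.5 or above 97.5. This describes these libraries and is not a test. Members of a list can vary together in a single culture, which random lists of other genes do not reproduce. The list symbols Ccn1 and Ccn2 were matched to Cyr61 and Ctgf through synonyms in the RefSeq table of GRCm38.p6, and Flg was not matched.

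Genes named in the text follow a rule fixed at the same time. It takes, per comparison, the 10 highest and 10 lowest log2 fold changes past the size rule with at least 10 CPM in the higher library, leaving out predicted, small RNA and mitochondrial genes. It adds up to 4 members per list with the largest change in any comparison and at least 5 CPM in any library, the 8 genes per direction with the largest opposite changes, and a fixed set of genes of interest; some results it allows are not reported here. Krt5, Krt14, Cdh1, Epcam and Ptprc are given as counts because they stayed under the filter; Epcam, Ptprc, Hspb1 and Psmb8 were chosen after their values were seen. Coordinates are those of the deposited table in mm10, counted from 1.

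Overlaps and correlations that share a library were set beside 20 simulations of unchanged libraries each with Poisson counting error alone or with a coefficient of variation of 0.2 or 0.4, and beside the overlap of independent lists. The TPA reads were also split at random into 2 equal parts, 20 times. Gains of silent gene families were compared with an interval from 2000 bootstrap resamples of genes. Alternatives for the counts were total-count, DESeq2 1.42.0 median-of-ratios and upper-quartile scaling, no filter or a filter at 5 CPM, size rules at 1.5-fold and 4-fold, prior counts of 0.5 and 5, intervals widened by an assumed coefficient of variation of 0.1, 0.2 or 0.4, and thinning to the smallest library. Chosen after seeing the data were the removal of a lowess trend (span 0.3, statsmodels 0.14.6) with the GC content of the longest GENCODE transcript, a correction of counts for duplicate removal, leaving out silent genes beside the end of an expressed gene, and a mean of at least 10 CPM. GC content was known for 96.2% of the genes past the filter.

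The size rule was tested on simulated Poisson counts drawn from the means and sizes of these libraries, with 200 genes changed per comparison. In TPA against control, run on 12752 genes, it called 4.0% of 50 genes changed 1.5-fold, 96.0% of 50 changed 3-fold, all 50 changed 4-fold, and 0.48% of the unchanged genes. In CDDO+TPA against TPA, on 12788 genes, it called 4.0% of those changed 1.5-fold, 100.0% of those changed 3-fold and 0.44% of the unchanged genes. In CDDO+TPA against control, on 12745 genes, it called 0 of those changed 1.5-fold, 96.0% of those changed 3-fold and 0.43% of the unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.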

Results

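RNA sequencing counts were analysed for mouse JB6 P+ cells, an epidermal line, labelled as epithelial cells of the skin, in which tumour promoters induce transformation. There were 3 libraries, 1 per group: a control, cells given the phorbol ester TPA at 10 ng/mL, and cells given TPA at the same dose together with 50 nM CDDO, a synthetic oleanane triterpenoid. Both treatments were repeated on alternate days over 5 days in medium with 1% serum. The control, TPA and CDDO+TPA libraries held 8190078, 7813035 and 7872089 reads assigned to genes, and 15133, 15956 and 15497 of the 24421 genes had at least 1 read. The 13100 genes with at least 1 CPM in at least 1 library were compared, CPM being the read count of a gene scaled to the size of its library. No group had a replicate, so no difference below has a test against the spread between cultures, and each interval covers counting error only. CPM values are listed in the order control, TPA, CDDO+TPA. A gene was past the size rule when its log2 fold change was at least 1 in size and the 95% counting interval of its fold excluded 1.

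The comparison of TPA with control asks how expression differed in cells given the tumour promoter without CDDO. Whether the control culture was kept in the same low-serum medium, for the same time or with a vehicle is not given in the sources used here. Differences from control therefore cannot be assigned to TPA apart from serum, time in culture or vehicle. The complement and acute phase list was shifted downward in the TPA library, with 9 of 11 measured members lower, and the heat shock list upward, with 4 of 14 higher. Ptx3, a soluble pattern recognition protein, was 43.0-fold lower (95% counting interval 34.1 to 55.0) in the TPA library, and Lcn2, a siderophore-binding secreted protein, was 17.7-fold lower (11.4 to 28.9). Hspa1b, which encodes an inducible HSP70 chaperone, was 20.1-fold higher (17.0 to 23.8). It held 1.072 reads per exonic base in the TPA library, so a cap from duplicate removal by position may have narrowed this fold. The fibrillar collagen gene Col5a2 was 20.1-fold lower (17.5 to 23.1), with 557, 27.7 and 82.5 CPM. In all, 1254 genes were higher and 774 lower in the TPA library past the size rule.

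Among the genes with the largest differences, Atp13a4, a P5-type ATPase, had 1, 540 and 347 reads and was 543-fold higher (97.1 to 21500) in the TPA library. Lad1, an anchoring filament protein of the basement membrane, was 82.5-fold higher (27.9 to 403), and Celsr2, an adhesion receptor of planar cell polarity, was 39.6-fold higher (22.5 to 77.3). Adam33 and Siglec1, which lie near each other on the minus strand of chromosome 2, were 62.4-fold (16.9 to 521) and 42.6-fold (18.0 to 133) higher. Lad1 lies on chromosome 1, 135818598 to 135833341, plus strand, and Celsr2 on chromosome 3, 108390848 to 108415494, minus strand. Angpt2, a ligand of the endothelial receptor TEK, had 0.499, 20.7 and 3.42 CPM; it overlaps Mcph1 on the other strand. The chloride channel gene Best2 and the Rab5-exchange-factor-like gene Rinl were 29.8-fold (16.0 to 62.7) and 30.5-fold (15.8 to 67.5) higher. Rasgrf2, a RAS exchange factor, had 3, 136 and 8 reads, and the metallocarboxypeptidase-like gene Cpxm1 had 5, 185 and 8 reads. At the other end, Veph1 had 529, 0 and 51 reads, so that it was at least 175-fold lower in the TPA library against a floor of 3 counts. Veph1 (chromosome 3, 66053558 to 66296837, minus strand in mm10) spans Ptx3 (chromosome 3, 66219887 to 66225806, plus strand), which lies on the other strand. Svep1, an extracellular matrix protein, was 80.5-fold lower (43.6 to 169), and the aggrecanase gene Adamts5 was 56.5-fold lower (31.4 to 114). Exph5, a Rab27 effector, had 166, 6.65 and 22.8 CPM, and Fgf21, a stress-responsive hormone gene, had 20.2, 0.753 and 1.90 CPM. Acox2, Bpifc and Mamdc2 were also among the 10 lowest, with log2 fold changes of -4.29, -4.72 and -4.32.

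Several gene lists stood apart from random lists matched on mean expression. Here and below, such a percentile describes these libraries and does not measure the spread of a list between cultures. The complement and acute phase list had a median log2 fold change of -2.58, below all 10000 random lists, and of its 11 measured members 0 were higher, 9 lower and 2 not past the rule. With members at 0 counts set to their bound, the median of that list was -1.73. Saa3, an acute-phase apolipoprotein, had 75.4, 10.8 and 68.0 CPM, and Lbp, the lipopolysaccharide-binding protein, had 20.7, 1.26 and 3.17 CPM. Genes of cholesterol synthesis had a median of -0.72, below all 10000 random lists, and of 24 measured members 0 were higher, 7 lower and 17 not past the rule. Within that list Idi1, an isomerase of the mevalonate pathway, was 3.70-fold lower (2.99 to 4.61), and the sterol demethylase gene Cyp51 was 3.09-fold lower (2.67 to 3.60). Mesenchymal and fibroblast markers had a median of -0.45, below all 10000 random lists, and of 30 measured members 4 were higher, 9 lower and 17 not past the rule. Col1a1, the main chain of type I collagen, had 529, 152 and 267 CPM and Col3a1 had 50.2, 10.8 and 7.22 CPM, whereas Pdgfra, a PDGF receptor, had 5.24, 34.9 and 76.9 CPM and the proteoglycan gene Dcn had 8.49, 25.7 and 33.6 CPM. The intermediate filament gene Vim differed by a log2 fold change of 0.47.

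The heat shock list was shifted upward, with a median of 0.66, above all 10000 random lists; of 14 measured members 4 were higher, 0 lower and 10 not past the rule. Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned with certainty, were 18.7-fold (16.6 to 21.1) higher when summed, and the co-chaperone gene Dnajb1 was 2.60-fold higher (2.38 to 2.84). The remaining member past the rule was the small heat shock protein gene Hspb1, with 1, 25 and 1 reads. Glycolysis and hypoxia genes had a median of 0.34, percentile 99.98 (2 higher and 0 lower of 26 measured); Bnip3, a mitophagy receptor, was 2.73-fold higher (2.46 to 3.04), and Ankrd37, a HIF target, was 5.89-fold higher (3.32 to 11.2). The motility, adhesion and integrin list had a median of 0.22, percentile 99.45, which fell within the central 95% of random lists once the GC trend was removed, and of 24 measured members 5 were higher, 2 lower and 17 not past the rule. The leukocyte integrin gene Itgb7 had 36.8, 167 and 256 CPM and the laminin receptor gene Itga7 had 3.12, 28.9 and 2.66 CPM, whereas the collagen receptor gene Itga1 had 5.87, 0.879 and 6.21 CPM. Cytosolic ribosomal protein genes differed little, with a median of 0.13, percentile 98.0, and none of the 30 was past the size rule.

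Cytokine, chemokine and prostaglandin genes had a median of -0.42, percentile 0.13, and of 25 measured members 5 were higher, 6 lower and 14 not past the rule. Il6, an inflammatory cytokine, was 6.26-fold lower (3.19 to 13.7), and the chemokine genes Ccl9 and Ccl8 were 22.2-fold (7.28 to 110.4) and 3.51-fold (2.40 to 5.23) lower. Ptges, a prostaglandin E synthase, was 3.00-fold higher (2.54 to 3.55), whereas Ptgs2, the inducible cyclooxygenase, had 388, 372 and 588 CPM. Interferon response genes had a median of -0.35, percentile 0.6, and of 25 measured members 1 was higher, 4 were lower and 20 were not past the rule; the transcription factor gene Irf1 was 2.24-fold lower (1.95 to 2.57) and the RNA sensor gene Ddx58 was 2.01-fold lower (1.75 to 2.32), whereas the immunoproteasome gene Psmb8 had 4, 35 and 3 reads. Matrix proteases and their inhibitors went both ways, with a median of -0.32, percentile 1.81; of 19 measured members 4 were higher, 5 lower and 10 not past the rule. The stromelysin genes Mmp3 and Mmp10 were 6.30-fold (3.63 to 11.7) and 18.1-fold (6.77 to 68.2) higher, whereas Timp3, a metalloproteinase inhibitor, was 7.05-fold lower (5.79 to 8.67). The collagenase gene Mmp13 had 84.1, 99.8 and 166 CPM, and Mmp9 had 1, 9 and 1 reads. Cell cycle genes had a median of -0.25, percentile 1.64; of 38 measured members 2 were higher, 8 lower and 28 not past the rule, and Kif11, a spindle kinesin, was 3.96-fold lower (3.17 to 4.98).

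Other lists were not apart from random lists. The medians were 0.08, percentile 91.4, for NRF2 targets, which serve antioxidant and detoxifying functions, -0.23, percentile 10.3, for AP-1 components, -0.14, percentile 18.2, for the NF-kB pathway, 0.03, percentile 76.8, for CDK inhibitors and p53 targets, and 0.19, percentile 96.8, for EGF receptor ligands and ERK feedback genes. They were -0.12, percentile 21.1, for TGF-beta targets, -0.06, percentile 45.9, for the unfolded protein and integrated stress response, 0.03, percentile 60.0, for DNA methylation enzymes, 0.10, percentile 92.5, for histone deacetylases and methyltransferases, and -0.05, percentile 45.2, for nuclear oxidative phosphorylation genes. Single members still differed past the size rule. Gadd45g, a stress-inducible growth arrest gene, was 8.99-fold higher (6.66 to 12.4), and Btg2, a p53 target, was 2.20-fold lower (1.95 to 2.49). Tnfaip3, an NF-kB feedback inhibitor, was 2.38-fold higher (2.11 to 2.69), and the adhesion molecule gene Vcam1 was 3.41-fold lower (2.90 to 4.03). Dusp5, an ERK phosphatase, was 3.59-fold higher (2.56 to 5.14), the matricellular gene Ctgf was 2.76-fold lower (2.24 to 3.41) and Vldlr, a lipoprotein receptor, was 2.97-fold lower (2.73 to 3.24). Hdac4 and Hdac8, which encode histone deacetylases, were 2.68-fold (2.38 to 3.03) and 2.51-fold (2.03 to 3.12) lower. The AP-1 gene Fosl1 had 42.3, 52.98 and 51.1 CPM. The list of skin tumour promotion genes responsive to phorbol ester had a median of 0.34, at the upper limit of the central 95% of random lists and beyond it with total-count or upper-quartile scaling, or 0.20 with members at 0 counts set to their bound. In that list Prl2c2, a placental proliferin, had 0, 32 and 312 reads, the keratinocyte transglutaminase gene Tgm1 had 6, 61 and 2 reads, and Odc1, the first enzyme of polyamine synthesis, had 124, 125 and 174 CPM.

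Markers of keratinocytes were mostly undetected: 13 of 34 were measured, Krt5 and Epcam had 0 reads in every library, Krt14 had 1, 0 and 1, and Cdh1 had 4, 1 and 4. A count of 0 was set against a floor of 3 counts, which is 0.374, 0.377 and 0.380 CPM in the control, TPA and CDDO+TPA libraries. The 13 measured members had a median of 0.72, percentile 95.4; the desmosomal gene Pkp3 and the laminin receptor gene Itgb4 were 4.92-fold (3.23 to 7.74) and 8.09-fold (5.23 to 13.1) higher. Only 6 leukocyte markers were measured, with a median of -0.67, percentile 1.70 (2 higher and 2 lower of 6 measured), within the central 95% of random lists with a prior count of 5; Cd68, a lysosomal glycoprotein, had 22.1, 52.2 and 71.2 CPM, and Cd74, the invariant chain, had 23.6, 6.78 and 5.45 CPM. The pan-leukocyte marker Ptprc had 0 reads in every library. Of 4 measured endothelial markers, Vwf, the von Willebrand factor, had 49.9, 289.6 and 198 CPM and Egfl7 had 15.7, 11.2 and 19.4 CPM; the 4 had a median of 1.46. The 4 measured melanocyte and Schwann cell markers had a median of -0.21, and Mitf had 25.3, 15.9 and 35.2 CPM. Of the 1254 genes higher in the TPA library, 596 had under 1 CPM in control, and with a mean of at least 10 CPM required the counts were 381 higher and 476 lower, so that the majority changed side. With an assumed coefficient of variation of 0.4 between cultures in the interval, 651 were higher and 247 lower; without that widening, simulated unchanged libraries gave 27.7 higher and 25.4 lower with counting error alone, 189.6 and 182.6 at a coefficient of 0.2, and 1494 and 1490.4 at 0.4, the last pair above the observed counts.

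The comparison of CDDO+TPA with TPA asks what the triterpenoid added to the promoter. The cell cycle and NRF2 lists were shifted upward in the CDDO+TPA library, with 24 of 38 and 9 of 35 measured members higher. Mki67, a proliferation marker, was 5.38-fold higher (95% counting interval 4.96 to 5.85), and Kif11 was 9.69-fold higher (7.88 to 12.03). Nqo1, a quinone reductase and NRF2 target, was 7.24-fold higher (6.06 to 8.71), and Gsta4, a glutathione S-transferase, was 11.6-fold higher (8.67 to 15.9). Nqo1 lies on chromosome 8, 107388225 to 107403205, minus strand, and Mki67 on chromosome 7, 135689788 to 135716379, minus strand. Past the size rule, 1031 genes were higher and 1019 lower in the CDDO+TPA library.

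All 38 measured cell cycle genes had positive log2 fold changes, with a median of 1.19, above all 10000 random lists, and 24 were higher, 0 lower and 14 not past the rule. The kinetochore gene Cenpf was 8.42-fold higher (7.03 to 10.2), and the mitotic checkpoint kinase genes Bub1 and Bub1b were 7.30-fold (5.91 to 9.09) and 6.78-fold (5.35 to 8.68) higher. Ccnd1, which encodes cyclin D1, had 219.9, 336 and 379 CPM. CDK inhibitors and p53 targets had a median of -0.36, percentile 0.03 (1 higher and 2 lower of 18 measured); the pro-apoptotic gene Bbc3 was 2.84-fold lower (2.47 to 3.26), Cdkn2c, an INK4 inhibitor, was 2.21-fold higher (1.77 to 2.78), and Cdkn1a, which encodes p21, had 251, 263 and 212 CPM.

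NRF2 targets had a median of 0.39, above all 10000 random lists, and of 35 measured members 9 were higher, 0 lower and 26 not past the rule. Gsta1 had 0, 3 and 160 reads, Gsta2 had 0, 0 and 100 reads, and these near-identical copies summed with Gm3776 were 151-fold (51.4 to 735) higher. Slc7a11, the cystine transporter, was 3.27-fold higher (2.99 to 3.59), and Srxn1, the sulfiredoxin gene, was 2.02-fold higher (1.84 to 2.23). The glutathione synthesis genes Gclm and Gclc had 58.3, 80.5 and 136 CPM and 158, 206 and 239 CPM, below the size rule in this comparison, and the thioredoxin reductase gene Txnrd1 had 345, 274 and 499 CPM. Hmox1, the haem oxygenase gene, had 193, 187 and 199 CPM, with log2 fold changes of -0.04 in TPA against control and 0.09 in CDDO+TPA against TPA. Nfe2l2, which encodes NRF2, had 166, 111 and 134 CPM, and Keap1, its inhibitor, had 57.5, 80.8 and 77.9 CPM.

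The complement and acute phase list had a median of 1.18, above all 10000 random lists, with 6 of 11 measured members higher and none lower. Lcn2 was 12.9-fold higher (8.26 to 21.1), Ptx3 was 9.78-fold higher (7.67 to 12.6) and Saa3 was 6.30-fold higher (5.01 to 8.01). Cytokine, chemokine and prostaglandin genes had a median of 0.66, percentile 99.98; of 25 measured members 8 were higher, 1 lower and 16 not past the rule, with Ccl9 and Ccl8 17.8-fold (5.78 to 89.2) and 3.36-fold (2.30 to 5.03) higher. Il6 had 63, 10 and 10 reads, so that no difference between the TPA and CDDO+TPA libraries was detectable at this depth. Nos2, the inducible nitric oxide synthase, had 1, 0 and 15 reads and was at least 5.05-fold higher against the floor of 3 counts in the TPA library. Matrix proteases and their inhibitors had a median of 0.35, percentile 99.2 (4 higher and 2 lower of 19 measured); Adamts5 was 7.98-fold higher (4.25 to 16.6), Mmp10 was 3.75-fold lower (2.24 to 6.59) and Mmp3 had 1.87, 11.8 and 8.11 CPM. The skin tumour promotion list had a median of 0.49, percentile 99.45, with 6 of 14 measured members higher and 1 lower. The proliferin genes Prl2c2, Prl2c3, Prl2c4 and Prl2c5, near-identical copies, were 9.56-fold (6.89 to 13.6) higher when summed, and Tgm1 was 30.2-fold lower (8.02 to 255).

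AP-1 components had a median of -0.29, percentile 2.43 (0 higher and 0 lower of 10 measured), which turned to 0.03, percentile 65.8, after the trend with GC content was removed and fell within the central 95% of random lists with a filter at 5 CPM; Atf3, a stress-induced member, had 158, 101 and 64.7 CPM, and Jun had 306, 235 and 184 CPM. Heat shock genes had a median of -0.27, percentile 0.66 (0 higher and 1 lower of 14 measured), and Hspa1b was 1.82-fold lower (1.72 to 1.94), short of the size rule. With 1.072 reads per exonic base in TPA and 0.582 in CDDO+TPA, Hspa1b may fall short only because duplicate removal narrowed its fold. Enzymes of DNA methylation and demethylation had a median of 0.17, percentile 85.2. Within that list Uhrf1, which recruits DNMT1 to replicated DNA, was 3.83-fold higher (3.33 to 4.41), and the 5-methylcytosine dioxygenase genes Tet3 and Tet2 were 3.22-fold (2.94 to 3.53) and 2.11-fold (1.58 to 2.83) lower. Dnmt1, the maintenance methyltransferase, had 93.5, 117 and 229 CPM, Dnmt3a had 79.2, 72.3 and 55.4 CPM and Dnmt3b had 7.49, 6.65 and 8.36 CPM. Kmt2d, a histone H3 lysine methyltransferase, was 2.27-fold lower (2.16 to 2.38), within a list of histone deacetylases and methyltransferases whose median was -0.09, percentile 11.6.

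The remaining lists were not apart from random lists in this comparison. Their medians were -0.09, percentile 18.0, for the NF-kB pathway, 0.22, percentile 93.3, for the interferon response, 0.01, percentile 55.5, for EGF receptor ligands and ERK feedback genes, 0.16, percentile 76.9, for keratinocyte markers, and 0.06, percentile 75.0, for mesenchymal markers. They were -0.09, percentile 20.8, for TGF-beta targets, 0.10, percentile 62.2, for leukocyte markers, 0.22, percentile 92.7, for cholesterol synthesis, -0.14, percentile 3.21, for the unfolded protein and integrated stress response, and -0.06, percentile 19.6, for glycolysis and hypoxia genes. They were 0.04, percentile 63.8, for oxidative phosphorylation, 0.12, percentile 90.2, for motility and adhesion, and -0.15, percentile 3.70, for ribosomal proteins. The 4 endothelial markers had a median of -0.82, and the 4 melanocyte and Schwann cell markers 0.91, with Erbb3, a neuregulin receptor, 2.103-fold higher (1.53 to 2.91). Ereg, an EGF receptor ligand, was 2.30-fold higher (2.101 to 2.52), Tnfaip3 was 2.08-fold lower (1.85 to 2.34) and Smad7, a TGF-beta feedback inhibitor, had 72.4, 86.8 and 44.0 CPM.

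Outside the lists, Arnt2, a partner of bHLH-PAS factors, was 21.6-fold higher (8.97 to 67.9), Scara5, a ferritin receptor, was 27.2-fold higher (10.3 to 102), and the actin-bundling gene Lcp1 was 13.6-fold higher (6.92 to 30.4). The kininogen gene Kng2 had 27, 6 and 130 reads. Among the lowest, Celsr2 and Lad1 were 93.7-fold (39.9 to 290) and 81.2-fold (27.5 to 397) lower, Serpinf2, which encodes alpha-2-antiplasmin, was 23.4-fold lower (16.6 to 34.3), and Siglec1 was 42.0-fold lower (17.7 to 131). Igfals, an IGF-binding protein subunit, had 4, 95 and 3 reads, the actin-binding villin gene Vil1 had 7, 86 and 1 reads, and Rem2, a small GTPase, had 5, 85 and 2 reads. Upstream of Celsr2, Best2, Rinl, Serpinf2, Itgb4, Itgb7, Rem2, Tgm1, Nqo1, Dnmt1, Hdac8, Phlda1 and Cd68, an expressed gene ended within 10 kb on the same strand. Downstream of Igfals and Nos2, both under 1 CPM in control, an expressed gene ended within 10 kb on the other strand. Restricting the counts to genes with a mean of at least 10 CPM left 522 higher and 227 lower. At an assumed coefficient of variation of 0.4 the counts were 399 higher and 555 lower; without that widening, simulated unchanged libraries gave 192.8 higher and 185.4 lower at 0.2 and 1493.8 and 1496.5 at 0.4, the last pair above the observed counts.

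**Figure D1:**
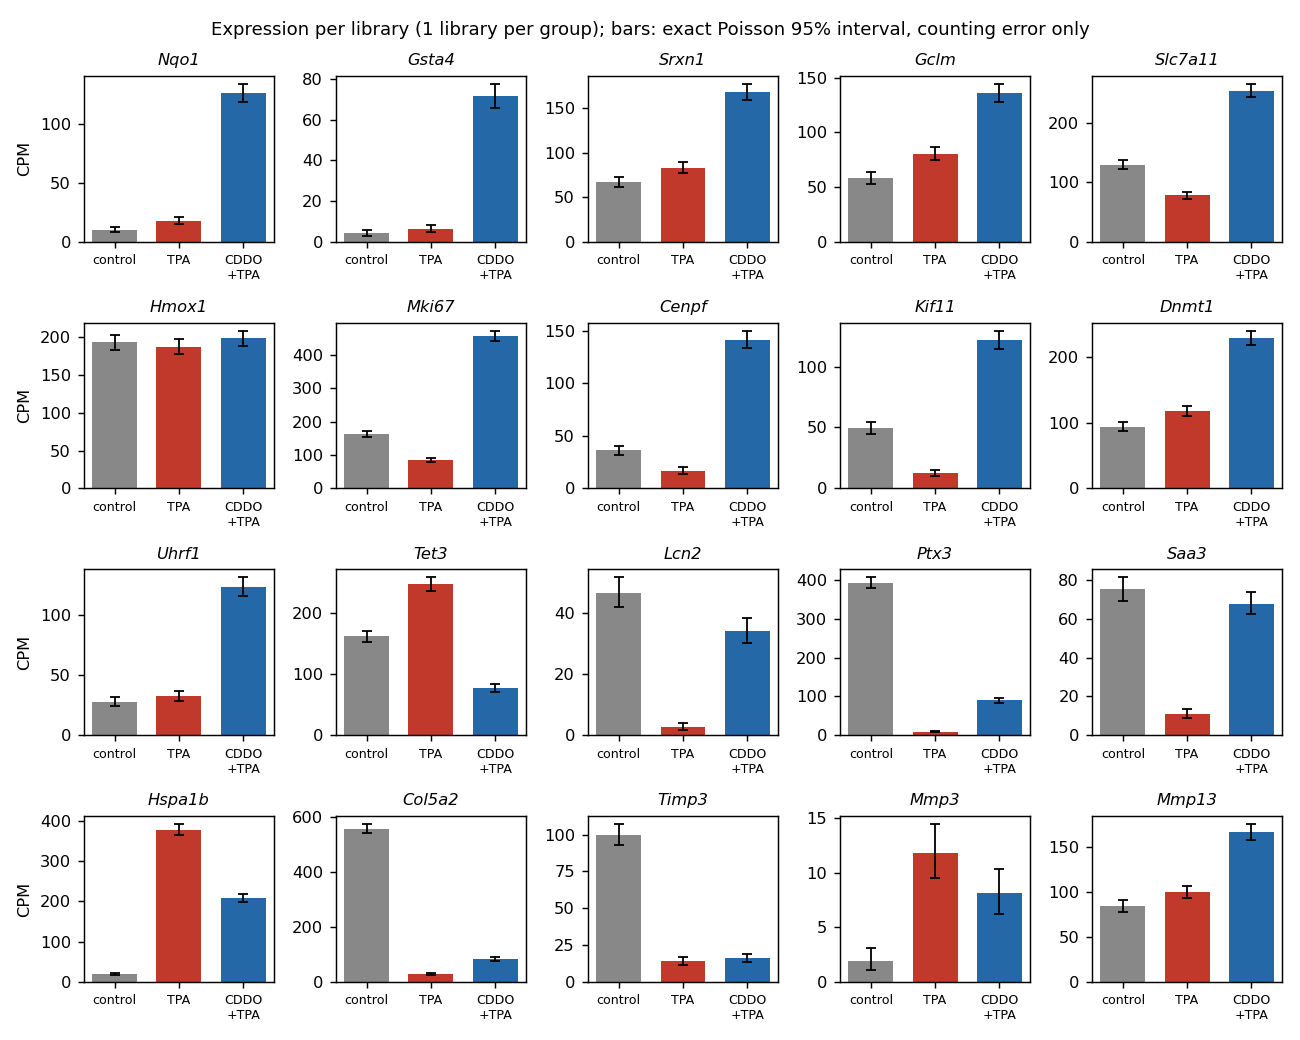
Expression of 20 genes named in the text in CPM (vertical axes, starting at 0) in the control, TPA and CDDO+TPA libraries, 1 library per group; error bars are exact Poisson 95% intervals and cover counting error only. Nqo1 stood at 9.98, 17.4 and 126 CPM, Mki67 at 162, 85.2 and 459 CPM, and Hmox1 at 193, 187 and 199 CPM.

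Genes that differed in opposite directions in these comparisons moved away from control in TPA and the other way in CDDO+TPA. Some did not stop near control but passed it, such as Kif11 with 398, 100 and 960 reads. Among the genes low in the TPA library and higher with CDDO were the acute-phase genes Lcn2 and Ptx3, the matrix protein gene Svep1, and Veph1. Lcn2 had 46.5, 2.64 and 34.0 CPM, Svep1 had 101, 1.26 and 17.5 CPM, and the scavenger receptor gene Scara5 had 8.99, 0.502 and 13.7 CPM. Atp2a3, an endoplasmic reticulum calcium pump, had 51.8, 2.51 and 24.3 CPM, and the membrane transporter gene Mfsd6 had 39.2, 4.39 and 31.3 CPM. In the other direction Celsr2, Lad1, Siglec1, Best2, Rinl, Cpxm1, Rasgrf2 and Igfals were high in the TPA library alone, with Lad1 at 3, 246 and 3 reads and Celsr2 at 12, 473 and 5 reads.

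There were 659 genes higher in TPA than in control and lower in CDDO+TPA than in TPA, and 347 genes with the reverse. Independent lists of these sizes would share 98 and 60.9 genes. Both comparisons use the same TPA library, which makes opposite changes by itself: simulated unchanged libraries gave 3.1 and 4.2 genes with counting error alone, 24.0 and 40.8 with a coefficient of variation of 0.2, and 427.9 and 609.8 with 0.4. The observed 659 lay above the simulated 427.9 and the observed 347 below the simulated 609.8. A variation of 0.4 between cultures would alone give numbers of this order, but with the larger count in the other direction. Among genes with a mean of at least 10 CPM the counts were 107 and 209, so that the majority changed side. Across the 13100 genes, which are not independent replicates, the log2 fold changes of both comparisons had a covariance of -0.54 and a correlation of -0.65. The simulated covariances were -0.03, -0.11 and -0.38, and the simulated correlations -0.51, -0.50 and -0.50. With the TPA reads split at random into 2 equal parts, 1 for each comparison, the covariance was -0.48. Over the 9890 genes with a mean of at least 10 CPM the covariance was -0.24 and the correlation -0.61, where simulated covariances were -0.01, -0.09 and -0.37. The observed value there was smaller in size than that at 0.4, so a uniform variation of 0.4 overstates the spread of these genes. The actual spread between cultures was not measured. Part of the overlap can come from the shared TPA library, which could not be split into separate libraries.

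**Figure D2:**
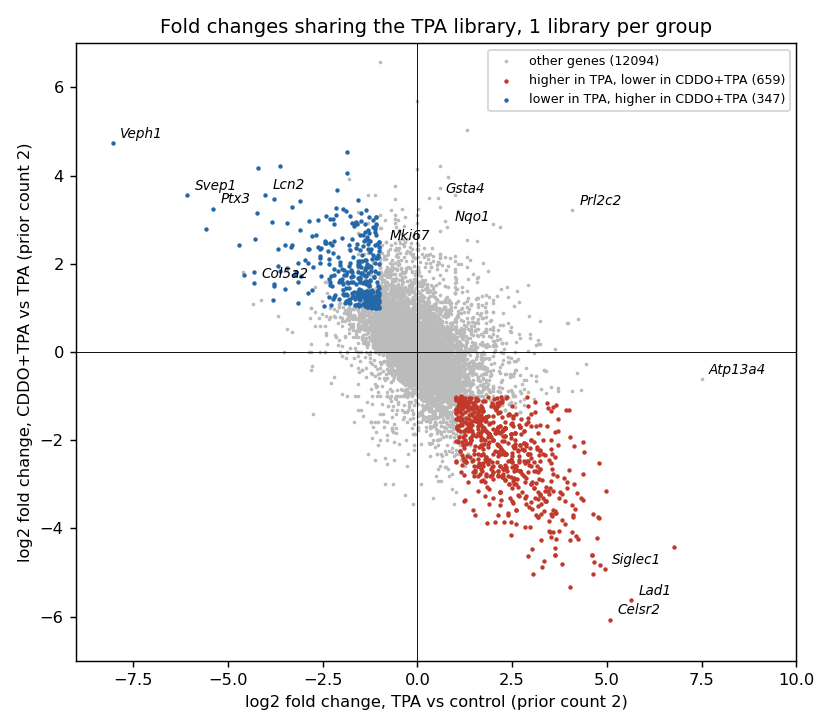
Log2 fold change of TPA against control (horizontal axis) and of CDDO+TPA against TPA (vertical axis) for 13100 genes, 1 library per group. Red points are the 659 genes higher in TPA and lower with CDDO, blue points the 347 genes with the reverse, and the TPA library enters both axes.

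The comparison of CDDO+TPA with control asks which differences stood after both agents together. The cell cycle list was shifted above control, with 22 of 38 measured members higher, as was the NRF2 list, with 9 of 35, and the cholesterol synthesis list was shifted below it, with 7 of 24 lower. Mki67 was 2.82-fold higher (95% counting interval 2.65 to 3.01) and Nqo1 was 12.7-fold higher (10.1 to 16.1), whereas Col5a2 was 6.75-fold lower (6.22 to 7.34) and Timp3 was 6.22-fold lower (5.15 to 7.56). Past the size rule, 1051 genes were higher and 442 lower in the CDDO+TPA library.

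All 38 measured cell cycle genes had positive log2 fold changes here too, with a median of 1.14, above all 10000 random lists. Of these, 22 were higher, 0 lower and 16 not past the rule. The comparison with TPA uses the same CDDO+TPA library, so its cell cycle and NRF2 shifts are not independent of those against control. Cenpf was 3.93-fold higher (3.45 to 4.49) and Kif11 was 2.45-fold higher (2.18 to 2.76). NRF2 targets had a median of 0.60, above all 10000 random lists, with 9 of 35 past the rule and higher; Gsta4 was 17.4-fold higher (12.2 to 25.5), Gclm 2.34-fold higher (2.095 to 2.61) and Srxn1 2.503-fold higher (2.26 to 2.77). Cholesterol synthesis genes had a median of -0.66, below all 10000 random lists, and 0 were higher, 7 lower and 17 not past the rule; Insig1, a sterol-regulated retention protein, was 3.05-fold lower (2.58 to 3.61). The complement and acute phase list had a median of -0.46, percentile 0.2 (0 higher and 4 lower of 11 measured); Ptx3 remained 4.40-fold lower (4.05 to 4.78), whereas Saa3 differed by a log2 fold change of -0.15. Heat shock genes had a median of 0.39, above all 10000 random lists (3 higher and 0 lower of 14 measured); Hspa1a and Hspa1b summed were 10.2-fold (9.05 to 11.6) higher, and Cryab, a small heat shock protein gene, was 2.30-fold higher (2.01 to 2.65).

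The mesenchymal list had a median of -0.19, percentile 1.79, within the central 95% of random lists with a filter at 5 CPM or the GC trend removed, and 3 were higher, 7 lower and 20 not past the rule; Col3a1 was 6.95-fold lower (5.25 to 9.34), whereas Pdgfra was 14.7-fold higher (10.7 to 20.6). The skin tumour promotion list had a median of 0.47, percentile 99.7 (5 higher and 0 lower of 14 measured). Against the floor of 3 counts in control, Prl2c2 was at least 106-fold higher and Prl2c5 was at least 20.98-fold higher. The 95% counting interval of the Prl2c2 fold began lower, at 85.4. EGF receptor ligands and ERK feedback genes had a median of 0.24, percentile 99.6 (5 higher and 0 lower of 22 measured); Dusp5 was 6.88-fold higher (4.998 to 9.67), the EGF receptor ligand gene Btc was 3.87-fold higher (2.58 to 5.94), and Phlda1 was 2.04-fold higher (1.83 to 2.28). Glycolysis and hypoxia genes had a median of 0.25, above all 10000 random lists (1 higher and 0 lower of 26 measured), and motility and adhesion genes 0.11, percentile 98.6 (3 higher and 1 lower of 24 measured); Itgb7 was 6.96-fold higher (6.16 to 7.89), and L1cam, a neural adhesion molecule, was 7.56-fold lower (5.35 to 10.96). AP-1 components had a median of -0.40, percentile 0.19 (0 higher and 1 lower of 10 measured), and Atf3 was 2.44-fold lower (2.20 to 2.71). The NF-kB list had a median of -0.25, percentile 1.33 (0 higher and 1 lower of 19 measured), CDK inhibitors and p53 targets -0.26, percentile 0.62 (1 higher and 1 lower of 18 measured), and the unfolded protein and integrated stress response -0.22, percentile 0.61 (0 higher and 0 lower of 26 measured). Bbc3 was 3.10-fold lower (2.71 to 3.56) and Vcam1 was 2.29-fold lower (1.98 to 2.64).

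Matrix proteases and their inhibitors had a median of 0.20, percentile 98.0 (4 higher and 2 lower of 19 measured), within the central 95% of random lists with the GC trend removed, with Mmp3 4.33-fold higher (2.44 to 8.19). Cytokine, chemokine and prostaglandin genes had a median of 0.32, percentile 97.7 (6 higher and 1 lower of 25 measured), which turned to -0.11, percentile 26.8, over the 15 members with at least 5 CPM and fell within the central 95% of random lists with a prior count of 0.5 or the GC trend removed; Ptges was 2.93-fold higher (2.48 to 3.48) and Il6 was 6.21-fold lower (3.16 to 13.6). Keratinocyte markers had a median of 0.72, percentile 98.4 (3 higher and 0 lower of 13 measured), within the central 95% of random lists with a filter at 5 CPM; Pkp3 was 4.89-fold higher (3.21 to 7.70) and Grhl2, an epithelial transcription factor gene, was 4.28-fold higher (2.36 to 8.30). The 6 leukocyte markers had a median of -0.57, percentile 2.06 (1 higher and 1 lower of 6 measured), within the central 95% of random lists with a prior count of 5, with Cd68 3.22-fold higher (2.72 to 3.84) and Cd74 4.33-fold lower (3.10 to 6.18). The medians of lists not apart from random lists were -0.02, percentile 37.7, for the interferon response, -0.09, percentile 27.4, for TGF-beta targets, -0.01, percentile 54.1, for DNA methylation enzymes, 0.03, percentile 85.8, for histone deacetylases and methyltransferases, 0.03, percentile 87.5, for oxidative phosphorylation, and -0.01, percentile 81.0, for ribosomal proteins. Within the DNA methylation list, Uhrf1 was 4.43-fold higher (3.83 to 5.15), Dnmt1 was 2.45-fold higher (2.25 to 2.67) and Tet3 was 2.11-fold lower (1.91 to 2.32). The 4 endothelial markers had a median of 0.56, and the 4 melanocyte and Schwann cell markers 0.36.

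Among the largest single differences, Atp13a4 was 352-fold higher (62.8 to 13960), Slc35f1, a solute carrier gene, was 61.9-fold higher (16.8 to 517), and the leukocyte tetraspanin gene Cd53 was 39.9-fold higher (18.1 to 109.9). Notch4 had 4, 92 and 145 reads, the myeloid receptor gene Cd300lb had 3, 75 and 119 reads, and the mast cell protease gene Mcpt8 had 2, 28 and 83 reads. Among the lowest, Acsm2, an acyl-CoA synthetase, was 18.7-fold lower (8.34 to 52.1), the endocytic receptor gene Lrp2 was 8.52-fold lower (5.35 to 14.3), and Dpt, which encodes dermatopontin, was 8.40-fold lower (5.07 to 14.8). Edn1, which encodes endothelin-1, had 13.4, 1.13 and 1.65 CPM, and the phosphate transporter gene Slc34a1 had 12.7, 5.52 and 1.52 CPM. TPA and CDDO+TPA shared 378 genes higher than control and 181 lower, where independent lists would share 100.6 and 26.1. Unchanged libraries compared with the same control shared 5.2 and 2.8 genes in simulation with counting error alone, 40.8 and 20.8 at a coefficient of variation of 0.2, and 611.2 and 426.9 at 0.4. With an assumed coefficient of variation of 0.4, 450 genes were higher and 158 lower in CDDO+TPA than in control, and with a mean of at least 10 CPM required, 507 and 165. Simulated unchanged libraries gave 184.0 higher and 184.4 lower at 0.2 and 1493.8 and 1488.0 at 0.4 without that widening, the last pair above the observed counts. The medium and any vehicle of the control culture are not given in the sources used here, so serum and agent effects cannot be separated against control.

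**Figure D3:**
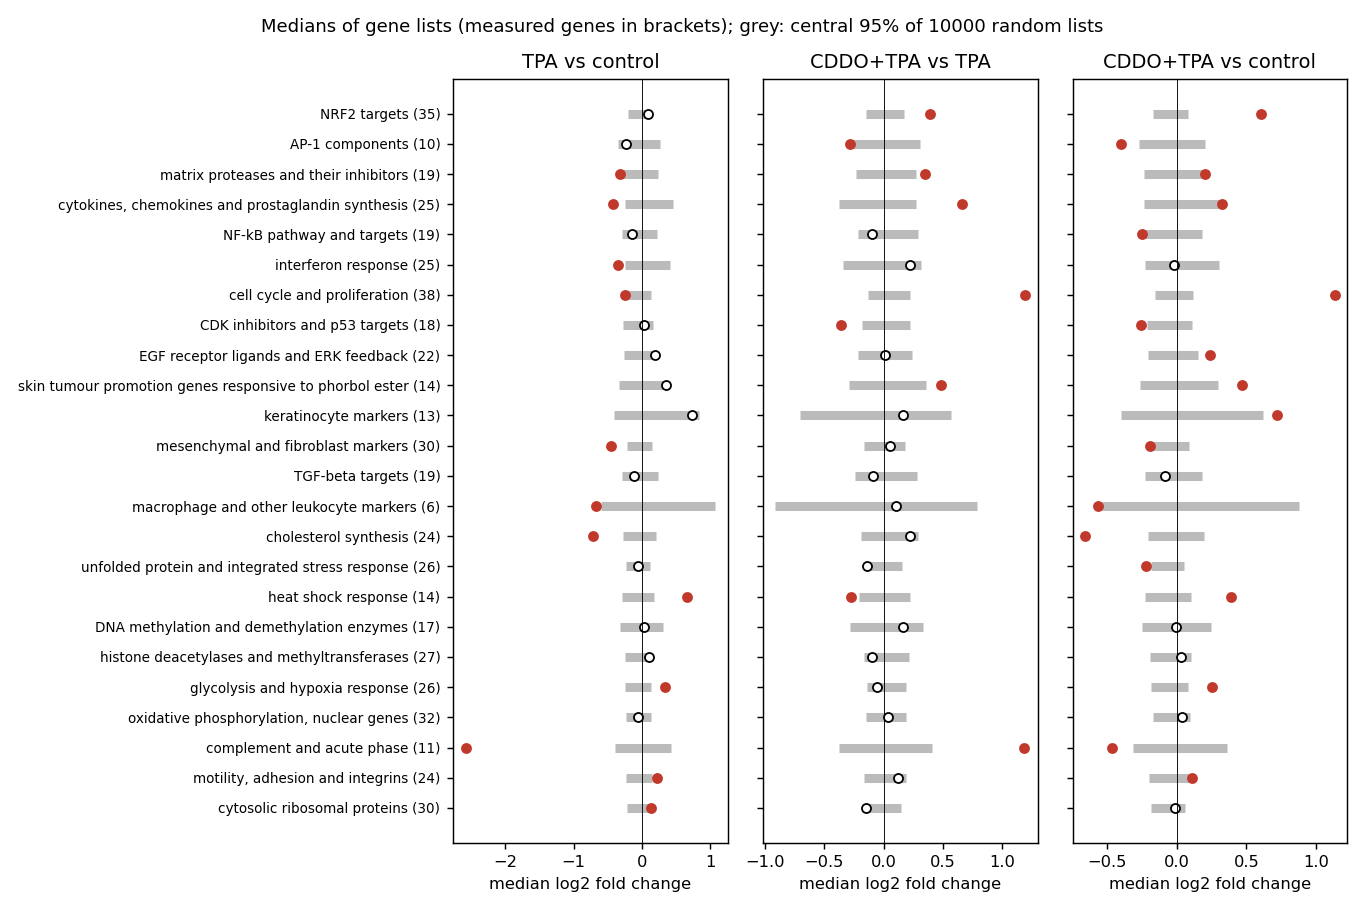
Median log2 fold change of 24 gene lists (horizontal axes) in each comparison, 1 library per group; grey bars span the central 95% of the medians of 10000 random lists matched on mean expression, and red points lie outside it by percentile. Cell cycle genes stood at -0.25, 1.19 and 1.14, and complement and acute phase genes at -2.58, 1.18 and -0.46, in TPA against control, CDDO+TPA against TPA and CDDO+TPA against control.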

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

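Removal of the GC trend, the correction for duplicate removal, the omission of silent genes beside an expressed gene and the restriction to a mean of 10 CPM were chosen after seeing the data; the other settings were fixed before. No paired analysis was possible because each group holds 1 library, and no replicate could be left out. All 8 counts of genes (higher and lower in each comparison, and opposite changes in each direction) stayed within 1.5 times their reported values under total-count, median-of-ratios and upper-quartile scaling. The same held with no filter, with prior counts of 0.5 and 5, with an assumed coefficient of variation of 0.1 or 0.2, with thinning, with the GC trend removed, with the duplicate correction and without the silent genes. Splitting the TPA reads kept both counts of opposite changes within that limit. The counts moved with the size rule itself, with low-abundance genes and with a large assumed spread between cultures. Thinning to the smallest library says little on depth, since the totals were already close, and genes with few reads have the widest counting intervals. The other scalings say little too, because their factors lay close to those of TMM. For control these were 1 by total count, 0.982 by median of ratios and 1.002 by upper quartile, against 0.978 by TMM.

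At a size rule of 1.5-fold there were 2036 genes higher and 1797 lower in TPA than control, 2001 higher and 1683 lower in CDDO+TPA than TPA, 1757 higher and 1140 lower in CDDO+TPA than control, and 1037 and 930 genes with opposite changes. At 4-fold there were 540 genes higher and 147 lower in TPA than control, 274 higher and 443 lower in CDDO+TPA than TPA, 317 higher and 111 lower in CDDO+TPA than control, and 285 and 53 genes with opposite changes. With an assumed coefficient of variation of 0.4 there were 651 genes higher and 247 lower in TPA than control, 399 higher and 555 lower in CDDO+TPA than TPA, 450 higher and 158 lower in CDDO+TPA than control, and 349 and 82 genes with opposite changes, because the intervals were wider. Genes with a mean of at least 10 CPM gave 381 genes higher and 476 lower in TPA than control, 522 higher and 227 lower in CDDO+TPA than TPA, 507 higher and 165 lower in CDDO+TPA than control, and 107 and 209 genes with opposite changes, from 9890 genes. A filter at 5 CPM, which kept 11107 genes, moved the genes higher in TPA than control from 1254 to 711, the genes lower in CDDO+TPA than TPA from 1019 to 526, the genes lower in CDDO+TPA than control from 442 to 275 and the genes higher in TPA and lower with CDDO from 659 to 321.

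Of 39 list medians that stood apart, all kept their direction and their place under each of the 3 other scalings and the duplicate correction. The scalings had factors close to those of TMM and could move these medians little. The exceptions elsewhere were AP-1 components in CDDO+TPA against TPA, whose median turned from -0.286 to 0.026 with the GC trend removed, and cytokines, chemokines and prostaglandin synthesis in CDDO+TPA against control, whose median turned from 0.32 to -0.11 with the filter at 5 CPM, which left 15 of 25 members. The cause of the AP-1 change was not tested beyond that correction. A further 3 medians with the 5 CPM filter, 4 with the GC trend removed, 1 with a prior count of 0.5 and 2 with a prior count of 5 kept their direction but no longer stood apart, and with the 5 CPM filter both medians of the leukocyte list could not be given because too few members were left. Under the alternatives 11 medians came to stand apart that did not before, 4 of them the skin tumour promotion list in TPA against control. Of 474 log2 fold changes of named genes per setting, or 468 with the filter at 5 CPM, the duplicate correction moved 41 beyond their counting interval, removal of the GC trend 33, a prior count of 5 moved 10, and total-count and upper-quartile scaling 1 each, and none past the size rule changed sign.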

Other observations

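Serpin genes, which encode protease inhibitors and related proteins and were grouped after their values were seen, were mostly higher in the CDDO+TPA library. Of 26 measured genes with a Serpin name, 15 were higher and 3 lower in CDDO+TPA than in TPA past the size rule, with a median log2 fold change of 1.55, or 1.38 with members at 0 counts set to their bound. The group was picked for its high median among 179 groups of shared names, so its place among random lists is not given. Against control the median was 1.02. Serpinb9b, a relative of the granzyme B inhibitor Serpinb9, had 443, 202 and 1080 reads, and Serpinb9 itself had 158, 138 and 425 reads. Serpinb8 had 120, 81 and 300 reads and Serpinb1b had 24, 16 and 141 reads, whereas Serpinf2 and Serpind1, genes of plasma inhibitors made mainly by liver, were high in the TPA library alone, with 94, 781 and 33 reads and 0, 25 and 1 reads. Most of the 15 lie beside each other in the genome. Serpinb1a, Serpinb1b, Serpinb9 and Serpinb9b to Serpinb9g lie on chromosome 13 between 32842092 and 33496000. Serpina3f to Serpina3i lie on chromosome 12 between 104214544 and 104269365. The tally therefore does not stand for independent genes, and Serpina3f, Serpinb9d and Serpinb9f had 0 reads in the TPA library. The call of Serpina3f rests on 6 reads in the CDDO+TPA library. The Serpinb9 genes are close paralogs, so reads of single members are uncertain.

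A small group of genes stood in steps, higher in TPA than in control and higher again in CDDO+TPA than in TPA. It held 29 genes, fewer than the 98.7 that independent lists of these sizes would share. Simulated unchanged libraries gave 0 with counting error alone or a coefficient of variation of 0.2 and 18.4 at 0.4. The examples from this group were chosen after their values were seen. Prl2c2 and Pdgfra belong to it, as do the phosphatase gene Ptpn22 with 4, 29 and 83 reads, the kinase gene Sgk2 with 4, 35 and 93 reads and the cholesterol exporter gene Abca1 with 47, 108 and 300 reads. The reverse, lower at each step, held 8 genes, among them Slc34a1, against 60.2 for independent lists and 17.4 in simulation at 0.4.

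The tests below that set neighbours on the same strand against those on the other strand, that looked for genomic DNA, that asked whether the TPA library deviated without TPA, and that counted reads per base were chosen after their results were seen. Those on distance, GC content and split reads were chosen before their results were seen. Many genes with almost no reads in control had some in the TPA library: 596 of 5379 genes with a read in any library and under 1 CPM in control were past the size rule and higher in TPA, with a median of 18 reads against 2; 132 of the 596 were also higher in CDDO+TPA than in control, and 386 (64.8%) were lower in CDDO+TPA than in TPA. Genomic DNA is argued against as the whole cause. Olfactory, vomeronasal, hair keratin-associated and defensin genes under 1 CPM in control gained 0.153 times as many CPM per kb of exon as all other such genes. The bootstrap 95% interval of that ratio was 0.09 to 0.232, although genes with a read in these families numbered 50 in control and 85 in TPA. A GC trend shared by all genes past the filter is argued against. Once it was removed, 99.6% of the pattern genes with a GC value stayed past the rule. The 596 genes had a median GC content of 0.533, against 0.498 for genes past the filter. A GC effect confined to genes with few reads was not tested, because the trend was fitted over all genes. Transcription running on past the end of an expressed gene is a candidate explanation for part of the pattern. The share of genes higher in TPA was 27.8% where an expressed gene ended within 10 kb upstream on the same strand and 13.1% where one started within 10 kb upstream on the other strand, a ratio of 2.13, and it was 2.25 times as large within 2 kb as at 20 to 50 kb; in CDDO+TPA the first share was 3.94%. Where an expressed gene ended within 10 kb downstream on the other strand, the share was 17.4% in TPA and 5.49% in CDDO+TPA. With none of these 3 kinds of neighbour it was 8.29% in TPA. Counting without strand would also assign reads running on from such a downstream gene, so the 17.4% does not speak against read-through. What stays open is that 326 of the 596 genes had none of these 3 kinds of neighbour. The share also did not rise with the upstream neighbour's level (28.4%, 26.0% and 29.0% in the lowest, middle and highest tertile of its CPM). A TPA effect on these genes was not tested apart from the library.

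The TPA library stood apart from both others, which lay closer to each other: the variance of log2 values set to its own deviation was 0.539, against 0.293 for control and 0.288 for CDDO+TPA; over genes with a mean of at least 10 CPM the values were 0.241, 0.174 and 0.135, so that the gap narrowed. Counting error of the shared library is argued against as the whole cause of the opposite changes, because the covariance kept 0.895 of its size when the TPA reads were split into 2 parts. A GC trend shared by all genes is argued against too, because 90.0% of the genes with opposite changes and a GC value kept them once it was removed. A GC effect confined to genes with few reads was not tested. A reversal of TPA effects by CDDO and a deviation of this TPA culture or library that TPA did not cause cannot be told apart with 1 library per group, and each may contribute to the value of 0.539. Separate cultures of each group would decide between them.

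The highest density was 1.834 reads per exonic base, for Eef2 in the TPA library, and no gene in any library reached 2, the number of start positions that both strands offer per base. Removal of duplicates by position may therefore set a ceiling on the most abundant genes, and no biological explanation was tested. In TPA against control the SD of log2 fold changes was 0.54 for genes with 0.25 to 0.5 reads per base, 0.48 for 0.5 to 1 and 0.57 for 1 to 2, so that it was not narrower at the highest density; in CDDO+TPA against TPA it was 0.50, 0.41 and 0.38.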
